A study of Mus musculus with 8 samples.

How the data were processed

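RNA was measured in sorted germinal centre B cells of C57BL/6 mice, per the labels: 2 Ctrl libraries (Cre with intact Irf8) and 2 Irf8 cKO libraries (Cre with floxed Irf8), 1 of each in experiments 1 and 2. Per the labels' protocols, cells were flash frozen, total RNA was taken with the RNeasy Mini kit, amplified with the Ovation RNA-Seq System v2 because little RNA was at hand, and made into libraries with Nextera XT. The other 4 samples of the series, B cells cultured with 10 µg/mL lipopolysaccharide and sorted at 72 hours, were not analysed here. Nothing in the labels says that the replicates came from separate animals. The p-values thus rest only on the spread between these samples, taken partly or wholly across genes, and that spread may be technical.

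The authors deposited 1 table per experiment, with an RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library) for each library and RefSeq gene, made in the Wardrobe platform per the series design text. The aligner behind these values is not given in the sources used here. The submitters' processing notes name TopHat2, Cufflinks 2.2, Cuffdiff, DESeq and the builds mm9 and mm10, with no role for each, and the deposited coordinates are those of mm10. Per the file headers each table also holds a log2 ratio of Irf8 cKO over Ctrl and a p-value of the authors, from a comparison of 1 library with 1 library. Checked on the values, the authors' deposited log2 ratio equals the log2 of the RPKM ratio plus a constant, 0.205 in experiment 1 and 0.721 in experiment 2, within 0.05 for 97.1% and 96.3% of the genes with RPKM of 1 or more. The authors' p-value column is unadjusted. Each table has 23471 entries, and those sharing a symbol (2 symbols) were summed.

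Depth was estimated from single-transcript genes, whose low RPKM times length fall on multiples of the worth of 1 read. With the estimated totals, 68.0% to 69.9% of the low values came out whole within 0.1 reads, so whole reads were not recovered and no count model was run. The exonic share of a library is the sum of RPKM times transcript length, leaving out Rn45s. Transcript lengths and GC content came from GENCODE transcripts of GRCm38, the assembly of mm10, matched by RefSeq accession, and lengths covered 97.6% of entries. Of the entries matched by symbol to a RefSeq annotation of GRCm38, 54.1% had the same start, so the authors' annotation differs from that one. The totals, exonic reads and shares and the length trend rest on the GENCODE lengths and are approximate.

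The comparison was a linear model with the experiment as a block (1 residual degree of freedom), fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a trend in the variance, 2-sided) on log2(RPKM + 1), so that a ratio understates the change of low genes. Genes entered with RPKM of 1 or more in at least 2 libraries (6446 genes), and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. As deposited the prior degrees of freedom of eBayes were infinite, so each SE and p came from the variance trend over genes of similar level. A gene's own spread between experiments then had no weight. After median-of-ratios scaling, described below, the prior degrees of freedom were 6.44. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The experiment is a block because the labels number the experiments and each has its own table. As a check of the pairing, deviations from the group means of same-numbered libraries correlated at 0.377 as deposited and 0.331 after scaling. Correlations between the 4 libraries on the log2 scale ran from 0.908 to 0.961. The test, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

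The 32 gene lists cover IRF and partner factors, plasma cell, ER protein folding and unfolded protein response, germinal centre B cell, B cell identity, dark zone, light zone, MHC class II and class I antigen presentation, type I interferon response, p53 targets, proliferation, DNA repair in hypermutation and class switching, positioning and migration, NF-kB and CD40 response, BCL2 family, immunoglobulin genes, naive and marginal zone B cell, memory B cell, B cell receptor signalling, glycolysis, oxidative phosphorylation, MYC targets in ribosome biogenesis, cytosolic ribosomal proteins, replication-dependent histones and immediate early and heat shock genes, with markers of T cells, myeloid cells, dendritic cells, NK cells, erythroid cells and platelets, and stroma. The 26 lists with 5 or more tested genes were tested with camera in limma (preset correlation 0.01, adjusted over the 26 lists), and again with an estimated correlation. That estimate rests on the 1 residual degree of freedom of the blocked fit. It can hardly call any list, so a list that fails it is not shown to be unchanged. The fry test of limma was run as well and is given for called lists. Named genes are Irf8, 11 fixed regulators (other items fixed in advance are not reported here), and up to 10 genes per direction past the threshold with mean RPKM of 5 or more and the same sign in both experiments, by largest log2 ratio. Where fewer qualified, genes of the same level and sign agreement filled the places, ranked by the smaller of their within-experiment ratios. Rik, Gm and small RNA names were passed over. In each list, examples are among the 4 members with the largest such smaller ratio as deposited, and their RPKM are given as deposited. The downward shift of these values, described below, favours members that fall, so the examples do not stand for their list. After scaling some examples lie above 0.

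Median-of-ratios scaling divided each library by its median ratio to the geometric mean over genes, by factors of 1.28 and 1.14 for Ctrl 1 and 2, and 1.07 and 0.658 for the libraries labelled Irf8 cKO 1 and 2. Other alternatives were quantile normalization, pseudocounts of 0.1 and 5, no filter or RPKM of 5 or more, no block, no trend in the variance, the highest transcript value per symbol, an adjusted p under 0.1, a 2-fold limit in both experiments, and leaving out each experiment and each library. A library was left out without the block, so those ratios mix in the difference between experiments. Trends of the log2 values on transcript length or GC content were removed by loess (span 0.5) in each library. The fit was tested on simulated data for this comparison, with 6446 genes of which 200 were changed, 50 at each log2 fold of 1, 2, 3 and 4. With the libraries shifted as in the deposited RPKM, the values as given recovered 62.0% at log2 fold 1 and 100.0% at the larger folds, with 33 unchanged genes called lower and 0 called higher by limma. After median-of-ratios scaling 88.0%, 100.0%, 94.0% and 96.0% were recovered, with 5 unchanged genes called in each direction. Simulated without a library shift, 10 unchanged genes were called higher and 8 lower after scaling, and 4 and 6 as given. Beyond the shift the simulation held no outlying library, so its recovery is not the power of the real fit.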

Results

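Germinal centre (GC) B cells are the antigen-activated B cells that mutate and select their antibody genes. Their transcriptomes were measured by RNA sequencing in C57BL/6 mice of 2 genotypes. Control mice (Ctrl) carried Cre recombinase and intact Irf8 alleles, and conditional knockout mice (Irf8 cKO) carried the same Cre with Irf8 flanked by loxP sites. B220-positive cells with high FAS and high GL7 were sorted 13 days after immunization with NP-KLH, a hapten on a carrier protein. Each of 2 experiments gave 1 Ctrl and 1 Irf8 cKO library, so n = 2 per group. The series also holds 4 samples of B cells activated with lipopolysaccharide, which were not analysed here.

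The deposited RPKM do not state read totals. The spacing of low values gave estimated totals of 73.3 M and 63.4 M reads (M, mega) for Ctrl 1 and Ctrl 2, and of 76.2 M and 64.0 M for the libraries labelled Irf8 cKO 1 and 2. Annotated exons outside 45S ribosomal RNA held an estimated 9.30 M and 7.17 M of these reads in the Ctrl libraries, and 8.07 M and 4.53 M in the libraries labelled Irf8 cKO. That is 12.7% and 11.3% of the total for Ctrl 1 and 2, and 10.6% and 7.07% for the libraries labelled Irf8 cKO. The 45S precursor transcript Rn45s took 5.30% and 3.43% of the reads in Ctrl 1 and 2, and 5.01% and 9.75% in the libraries labelled Irf8 cKO. Genes at 1 RPKM or more numbered 6566 and 6433 in Ctrl 1 and 2, 6171 in the library labelled Irf8 cKO 1 and 4845 in the library labelled Irf8 cKO 2, so low values are least precise in the last.

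**Figure D1:**
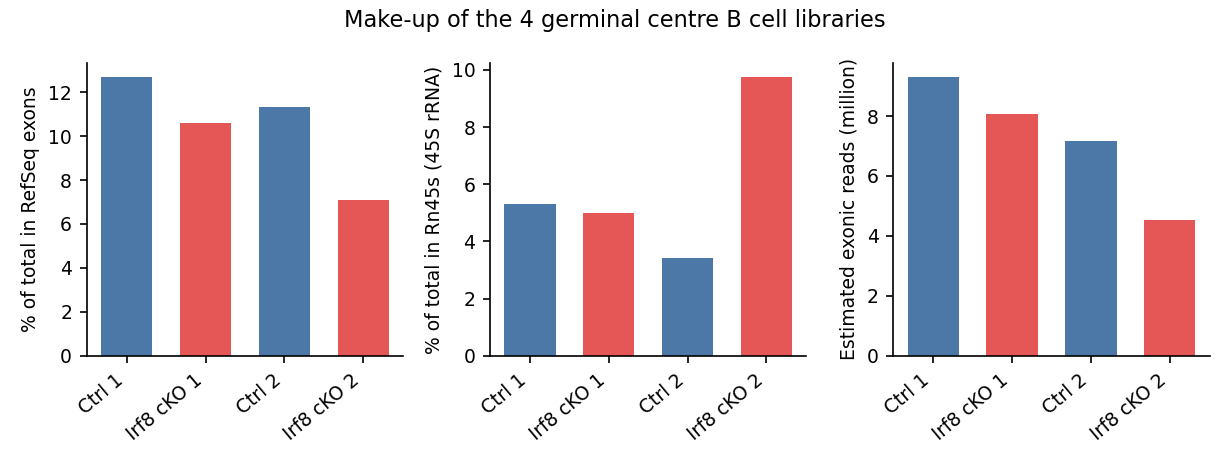
Bars give, for each of the 4 GC B cell libraries, the share of the read total in annotated exons, the share in Rn45s and the estimated number of exonic reads, in M. The library labelled Irf8 cKO 2 has the lowest exonic share, 7.07%, and the highest Rn45s share, 9.75%.

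Irf8 encodes an interferon regulatory factor of myeloid and B cells and is the gene the cross was designed to delete. Its transcript (NM_008320, chromosome 8, 120736376 to 120756692, plus strand, mm10) was not lower in the libraries labelled Irf8 cKO. It measured 14.5 RPKM in Ctrl 1 and 20.6 in the library labelled Irf8 cKO 1, and 14.9 in Ctrl 2 and 11.6 in the library labelled Irf8 cKO 2. The group values were 14.7 ± 0.288 in Ctrl and 16.1 ± 6.37 in the libraries labelled Irf8 cKO (mean ± SD, n = 2 each). The log2 ratio was 0.08 ± 0.35 (SE; limma, Benjamini-Hochberg adjusted p = 0.880), with 0.48 in experiment 1 and -0.33 in experiment 2. After median-of-ratios scaling it was 0.56 ± 0.18 (adjusted p = 0.400), with 0.72 and 0.41 in the experiments. Without the library labelled Irf8 cKO 1 and without the block, the log2 ratio as deposited was -0.31. The authors' deposited table gives Irf8 a log2 ratio of 0.717 (p = 0.0237) in experiment 1 and 0.366 (p = 0.278) in experiment 2. Each table holds a single value per gene over all its exons, and which exons the loxP sites flank is not given in the sources used here. That value is not restricted to deleted exons and so does not check the genotype labels, and every direction given here is that of the libraries as labelled.

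The comparison of libraries labelled Irf8 cKO with Ctrl asks which transcripts of GC B cells depend on IRF8. Havcr1, which encodes the surface receptor TIM-1, fell from 12.6 ± 1.04 RPKM in Ctrl to 1.98 ± 1.28 in the libraries labelled Irf8 cKO (mean ± SD, n = 2 each). Kmo, which encodes a hydroxylase of the kynurenine pathway of tryptophan breakdown, fell from 5.37 ± 0.0634 to 0.855 ± 0.0272 RPKM. Gatm, which encodes the amidinotransferase that begins creatine synthesis, fell from 4.49 ± 0.920 to 0.302 ± 0.153 RPKM. Scgb1a1, a secretoglobin gene best known from airway club cells, rose from 0.246 ± 0.0625 to 2.05 ± 0.928 RPKM. Kmo, Gatm and Scgb1a1 lie outside the naming rule and were chosen after their values were seen.

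In the RPKM as deposited, 70 of 6446 genes fell and 6 rose in the libraries labelled Irf8 cKO (limma, Benjamini-Hochberg threshold 0.05), so that 92.1% of the calls were lower. These calls rest on a variance shared by genes of similar level, not on each gene's own spread. All genes together were displaced in these values: the median log2 ratio was -0.35, with -0.18 in experiment 1 and -0.51 in experiment 2. After median-of-ratios scaling, which sets this shift aside, 3 genes fell and 1 rose, of which 75% were lower. These were Havcr1 (log2 ratio -1.88 ± 0.18 SE), Gatm (-1.76 ± 0.19), Kmo (-1.43 ± 0.15) and Scgb1a1 (1.47 ± 0.15), each at an adjusted p of 0.0397, and all 4 are among the 76 called in the deposited RPKM. Fitted without the experiment as a block, 19 genes fell and 2 rose as deposited, and 4 fell and 2 rose after scaling. Leaving out Ctrl 1, Irf8 cKO 1, Ctrl 2 or Irf8 cKO 2 by label, without the block, gave 0, 1450, 5 and 13 lower genes and 0, 9, 0 and 4 higher genes as deposited, against 9, 0, 13 and 10 lower and 13, 1, 6 and 4 higher after scaling. At an unadjusted p under 0.05, limma gave 31 lower and 7 higher genes as deposited without Ctrl 1, 8 higher without Ctrl 2, and 253 lower after scaling without the library labelled Irf8 cKO 1. Without that library and after scaling, the log2 ratio was -1.52 for Gatm, -2.11 for Havcr1, -1.26 for Kmo and 1.36 for Scgb1a1 (adjusted p = 0.122, 0.0739, 0.169 and 0.0739).

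**Figure D2:**
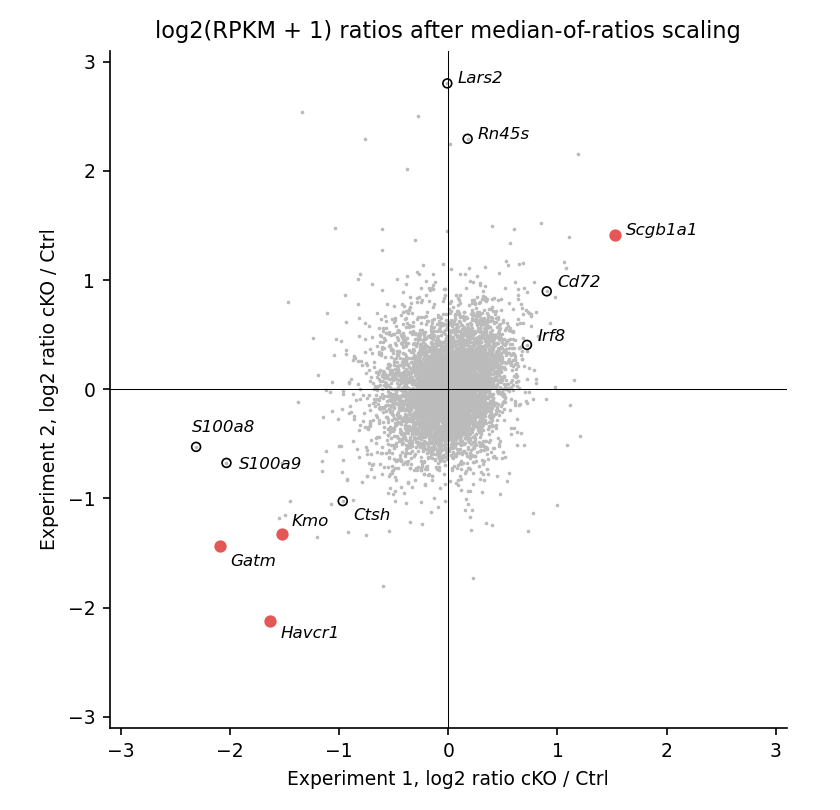
Each point is 1 of 6446 genes, with its log2 ratio of RPKM + 1 in experiment 1 on the horizontal axis and in experiment 2 on the vertical axis, libraries labelled Irf8 cKO over Ctrl, after median-of-ratios scaling. Red points are the 4 genes past the threshold (Havcr1, Gatm, Kmo and Scgb1a1) and open circles mark other genes named in the text, with Irf8 at 0.72 and 0.41.

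Of the other lower genes named by the rule, Ms4a1, which encodes the B cell surface protein CD20, fell from 82.0 ± 20.4 to 36.2 ± 18.1 RPKM, and Cd74, the invariant chain that escorts MHC class II, from 831.4 ± 71.1 to 385.8 ± 173.4 (mean ± SD, n = 2 each). Psmb8, a catalytic subunit of the immunoproteasome, fell from 21.1 ± 4.28 to 7.83 ± 2.73 RPKM. Ctsh, the lysosomal protease cathepsin H, fell from 16.0 ± 0.395 to 5.30 ± 1.63, and Ly86, the MD-1 partner of the receptor RP105, from 15.6 ± 4.79 to 5.95 ± 2.34. Atp5k, a subunit of mitochondrial ATP synthase, fell from 7.37 ± 1.56 to 2.81 ± 1.41. Rpl34-ps1, named as a pseudogene of ribosomal protein L34, fell from 29.1 ± 2.95 to 9.60 ± 5.19, a value that reads of its parent gene can inflate. Their log2 ratios as deposited were -1.23 for Ms4a1, -1.18 for Cd74, -1.34 for Psmb8, -1.46 for Ctsh, -1.27 for Ly86, -1.17 for Atp5k and -1.60 for Rpl34-ps1, with SE from 0.24 to 0.35 and adjusted p from 0.000186 to 0.0356 (limma, Benjamini-Hochberg). After scaling they were -0.72, -0.66, -0.86, -0.995, -0.81, -0.77 and -1.12 in the same order, all below 0 in both experiments, and none passed, with adjusted p from 0.128 to 0.666. Without Ctrl 1 and without the block, as deposited, the log2 ratios were -0.97, -1.09, -1.14, -1.43, -0.97, -0.98 and -1.50 in that order. That fit called 0 genes, with Havcr1 at -2.18 (adjusted p = 0.939), so the lost calls do not show that the 7 depend on Ctrl 1.

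The remaining lower genes named by the rule, S100a8 and S100a9, encode the calprotectin subunits abundant in neutrophils. S100a8 measured 26.0 RPKM in Ctrl 1 against 3.54 in the library labelled Irf8 cKO 1, and 1.69 in Ctrl 2 against 0.477 in the library labelled Irf8 cKO 2. S100a9 measured 21.8 against 3.64 and 2.26 against 0.575. Their log2 ratios were -1.72 ± 0.30 and -1.67 ± 0.30 as deposited (SE; adjusted p = 8.7e-06 and 2.0e-05), and -1.42 and -1.35 after scaling (adjusted p = 0.322 and 0.233). Without Ctrl 1 and without the block, the deposited log2 ratio was -0.05 for S100a8 and -0.27 for S100a9, and after scaling 0.13 and -0.06.

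The 6 higher genes in the deposited RPKM were Scgb1a1, Rn45s, Lars2, Snord68, Spata24 and A630023P12Rik, none of which met the naming rule. Rn45s measured 9085 and 5887 RPKM in Ctrl 1 and 2, and 8589 and 16716 in the libraries labelled Irf8 cKO. Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, measured 554 and 250 RPKM in Ctrl 1 and 2, and 461 and 1014 in the libraries labelled Irf8 cKO. Its values ranked the libraries in the same order as those of Rn45s. Whether reads counted for Lars2 stem from ribosomal RNA was not tested. Neither passed after scaling (adjusted p = 0.830 for Rn45s and 0.536 for Lars2), though the log2 ratios went from 0.71 to 1.24 for Rn45s and from 0.87 to 1.40 for Lars2. By experiment the scaled ratios were 0.18 and 2.29 for Rn45s and -0.0087 and 2.80 for Lars2. As deposited they were -0.08 and 1.51 for Rn45s and -0.27 and 2.01 for Lars2. The SE as deposited, 0.11 and 0.24, do not carry that spread between experiments. In their place the rule names 9 genes that did not pass the test, led by Cd72, an inhibitory B cell coreceptor, at 4.42 ± 0.896 RPKM in Ctrl and 6.43 ± 0.585 in the libraries labelled Irf8 cKO. Its log2 ratio was 0.46 ± 0.32 as deposited (adjusted p = 0.350) and 0.90 ± 0.15 after scaling (adjusted p = 0.137). The other 8 were Leng8, Arhgef1, Nfatc1, Fnbp4, Kmt2a, Ankrd11, Map4k2 and Depdc5. Their ratios ran from 0.08 (Depdc5) to 0.34 (Leng8) as deposited and from 0.53 (Depdc5) to 0.81 (Leng8) after scaling. Of these 9 genes all but Cd72 (1732 bases) had transcripts longer than the median over genes, 2884 bases. Of the lower genes named by the rule and with a known length, only Ms4a1 (3075 bases) did. The trend of the ratios on transcript length is given below.

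**Figure D3:**
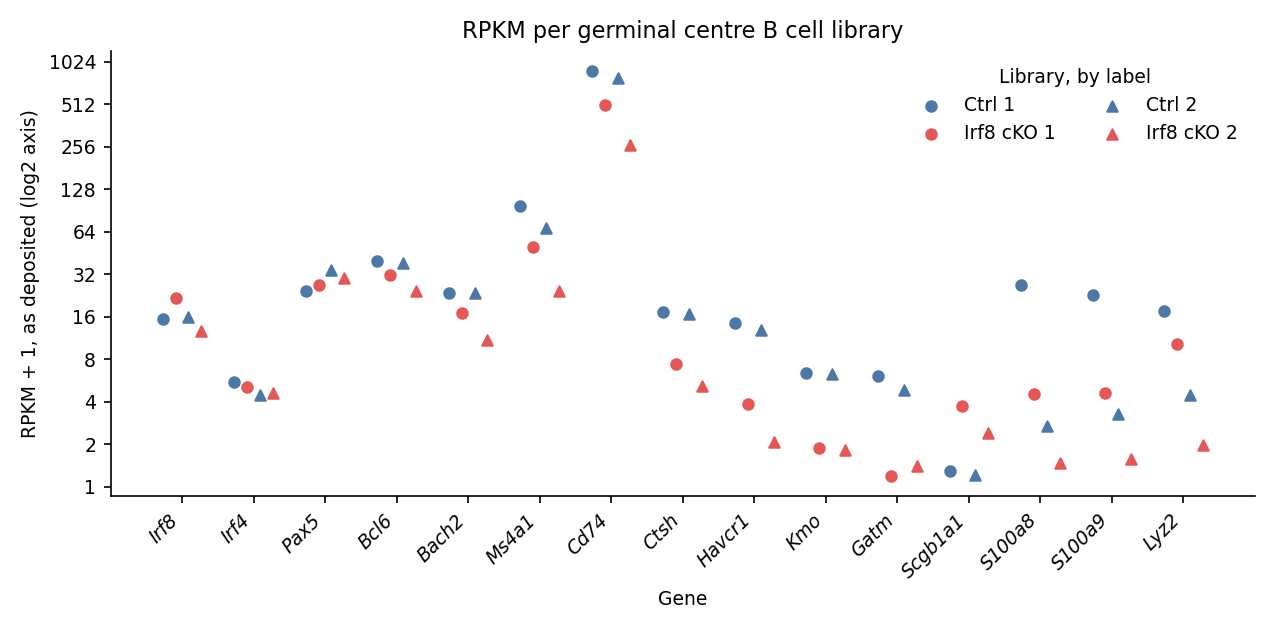
Points give RPKM + 1 as deposited, on a log2 axis, for 15 genes in each of the 4 libraries, blue for Ctrl and red for the libraries labelled Irf8 cKO, circles for experiment 1 and triangles for experiment 2. Havcr1, Kmo and Gatm separate the groups in both experiments, while S100a8 is highest in Ctrl 1, at 26.0 RPKM, and Irf8 overlaps between the groups.

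Of 11 regulators of B cell fate fixed in advance, 9 were tested and none passed. Irf4, the interferon regulatory factor that drives plasma cell formation, measured 3.99 ± 0.737 RPKM in Ctrl and 3.87 ± 0.331 in the libraries labelled Irf8 cKO (mean ± SD, n = 2 each). Its log2 ratio was -0.03 ± 0.30 as deposited and 0.39 ± 0.18 after scaling (adjusted p = 0.950 and 0.505, limma). Bcl6, the repressor that maintains the GC state, measured 38.2 ± 0.714 against 27.0 ± 5.05 RPKM. Its log2 ratio was -0.50 as deposited and 0.0080 after scaling. Pax5, the B lineage factor, measured 28.4 ± 6.92 against 27.4 ± 2.12 RPKM (log2 ratio -0.03, and 0.47 after scaling), and Bach2, a repressor of plasma cell genes, 22.5 ± 0.00919 against 13.1 ± 4.29 (-0.78, and -0.29 after scaling). Spi1, named Sfpi1 in the tables, and Spib encode the ETS partners of IRF8 and measured -0.26 and -0.60 as deposited, and 0.19 and -0.09 after scaling. Ciita, the MHC class II transactivator, measured -0.38 and 0.07, the plasma cell factor Xbp1 -0.40 and 0.05, and the p53 regulator Mdm2 -0.61 and -0.17. Irf4, Bcl6, Pax5, Spi1, Ciita and Xbp1 thus change sign with the scaling. The plasma cell genes Prdm1 and Sdc1 lay below the filter. Prdm1 measured 0.285 and 0.457 RPKM in Ctrl and 0.440 and 0.330 in the libraries labelled Irf8 cKO, and Sdc1 0.209 and 0.0774 against 0.0428 and 0.122.

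Among 26 gene lists with at least 5 tested members, 4 were lower than the other genes in the deposited RPKM (limma camera, Benjamini-Hochberg threshold 0.05), and 0 passed with an estimated correlation. That estimate rests on 1 residual degree of freedom and does not decide for or against a list. Oxidative phosphorylation, with an estimated correlation of -0.04, went from an unadjusted camera p of 0.00029 to 0.156. As deposited, the shift moves log2(RPKM + 1) less in low genes than in high ones. A list of highly expressed genes can thus lie lower in part by the shift alone. The differences after scaling, given for each list, set that shift aside. Of 14 tested genes of MHC class II antigen presentation, Cd74 fell and 13 did not pass, with 4 lower when adjusted over the list alone. H2-Aa, an MHC class II chain, measured 314.8 ± 47.1 RPKM in Ctrl and 160.8 ± 34.5 in the libraries labelled Irf8 cKO, and Ctss, the protease cathepsin S, 12.47 ± 5.20 against 5.88 ± 1.66 (mean ± SD, n = 2 each). The list lay -0.31 from the other genes on the log2 scale (adjusted p = 0.00286, and 0.992 with an estimated correlation). After scaling it lay at -0.21 (adjusted p = 0.233).

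Of 23 tested genes of oxidative phosphorylation, none passed and 3 were lower when adjusted over the list alone. Cox7a2, a cytochrome oxidase subunit, measured 6.33 ± 3.08 RPKM in Ctrl and 2.77 ± 1.93 in the libraries labelled Irf8 cKO, and Atp5g1, an ATP synthase subunit, 11.9 ± 4.47 against 5.17 ± 0.299 (mean ± SD, n = 2 each). The list lay -0.29 from the other genes (camera adjusted p = 0.00286, and 0.992 with an estimated correlation). It was the only list past the threshold after scaling, at -0.21 (adjusted p = 0.00812, and 0.972 with an estimated correlation), with -0.34 in experiment 1 and -0.08 in experiment 2. Of 26 tested cytosolic ribosomal protein genes, none passed and 0 did when adjusted over the list alone. Rps2 measured 39.8 ± 14.8 against 21.6 ± 8.94 RPKM and Rpl32 79.1 ± 5.81 against 45.3 ± 1.32. The list lay at -0.31 (adjusted p = 0.00286, and 0.992 with an estimated correlation), and after scaling at -0.17 (adjusted p = 0.0996), with -0.38 in experiment 1 and 0.05 in experiment 2. The fry test of limma, which asks whether a list moves on balance one way and compares it with no other genes, gave unadjusted p of 0.0282 for ribosomal proteins, 0.0593 for oxidative phosphorylation and 0.164 for MHC class II as deposited, and 0.603, 0.383 and 0.136 after scaling. Reads of ribosomal protein genes can be split with their many processed pseudogenes, so these values are uncertain. After scaling and without the block, leaving out Ctrl 1, Irf8 cKO 1, Ctrl 2 or Irf8 cKO 2 by label put oxidative phosphorylation at 0.02, -0.32, -0.45 and -0.11 (camera adjusted p = 0.942, 0.0294, 3.3e-07 and 0.336). In the same order ribosomal proteins lay at 0.02, -0.15, -0.36 and -0.19 (adjusted p = 0.942, 0.784, 0.000264 and 0.143), and MHC class II at -0.24, -0.13, -0.17 and -0.29 (adjusted p = 0.108, 0.7996, 0.290 and 0.0448). As deposited and without the block, the adjusted p in that order was 0.956, 0.0191, 0.00248 and 0.573 for oxidative phosphorylation, 0.734, 0.924, 0.376 and 0.704 for ribosomal proteins, and 0.599, 0.931, 0.711 and 0.273 for MHC class II.

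The fourth list past the threshold as deposited holds myeloid marker genes. Of 6 tested, S100a8 and S100a9 fell and 4 did not pass, with 3 lower when adjusted over the list alone. Lyz2, the lysozyme of macrophages and granulocytes, measured 16.5 and 3.47 RPKM in Ctrl 1 and 2 against 9.34 and 0.988 in the libraries labelled Irf8 cKO. Apoe, an apolipoprotein of macrophages and other cells, measured 9.04 and 7.86 against 6.75 and 5.90. After scaling the log2 ratio was -0.61 for Lyz2 and 0.10 for Apoe. The list lay -0.50 from the other genes as deposited (camera adjusted p = 0.000761, and 0.992 with an estimated correlation) and -0.52 after scaling (adjusted p = 0.133). Its unadjusted p from fry was 0.196 as deposited and 0.514 after scaling. By experiment the difference was -0.93 and -0.07 as deposited, and -0.90 and -0.13 after scaling. Without Ctrl 1 and without the block it was 0.14 as deposited and 0.11 after scaling, and without the library labelled Irf8 cKO 2 -0.29 and -0.28. Without the library labelled Irf8 cKO 1 it was -0.71 as deposited and -0.75 after scaling, and without Ctrl 2 -1.14 and -1.13. The neutrophil granule genes Ngp and Lcn2, chosen after their values were seen, were also highest in Ctrl 1, at 11.9 and 7.38 RPKM, against 3.72 and 1.46 in the library labelled Irf8 cKO 1, and measured 2.24 and 0.776 in Ctrl 2 against 0.107 and 0.0365 in the library labelled Irf8 cKO 2. After scaling the log2 ratios in experiments 1 and 2 were -1.20 and -1.35 for Ngp and -1.52 and -0.67 for Lcn2 (limma adjusted p over both = 0.0512 and 0.218). Without the block and after scaling, leaving out Ctrl 1, Irf8 cKO 1, Ctrl 2 or Irf8 cKO 2 by label gave -0.36, -2.23, -2.15 and -0.31 for Ngp and -0.08, -1.66, -2.07 and -0.53 for Lcn2.

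**Figure D4:**
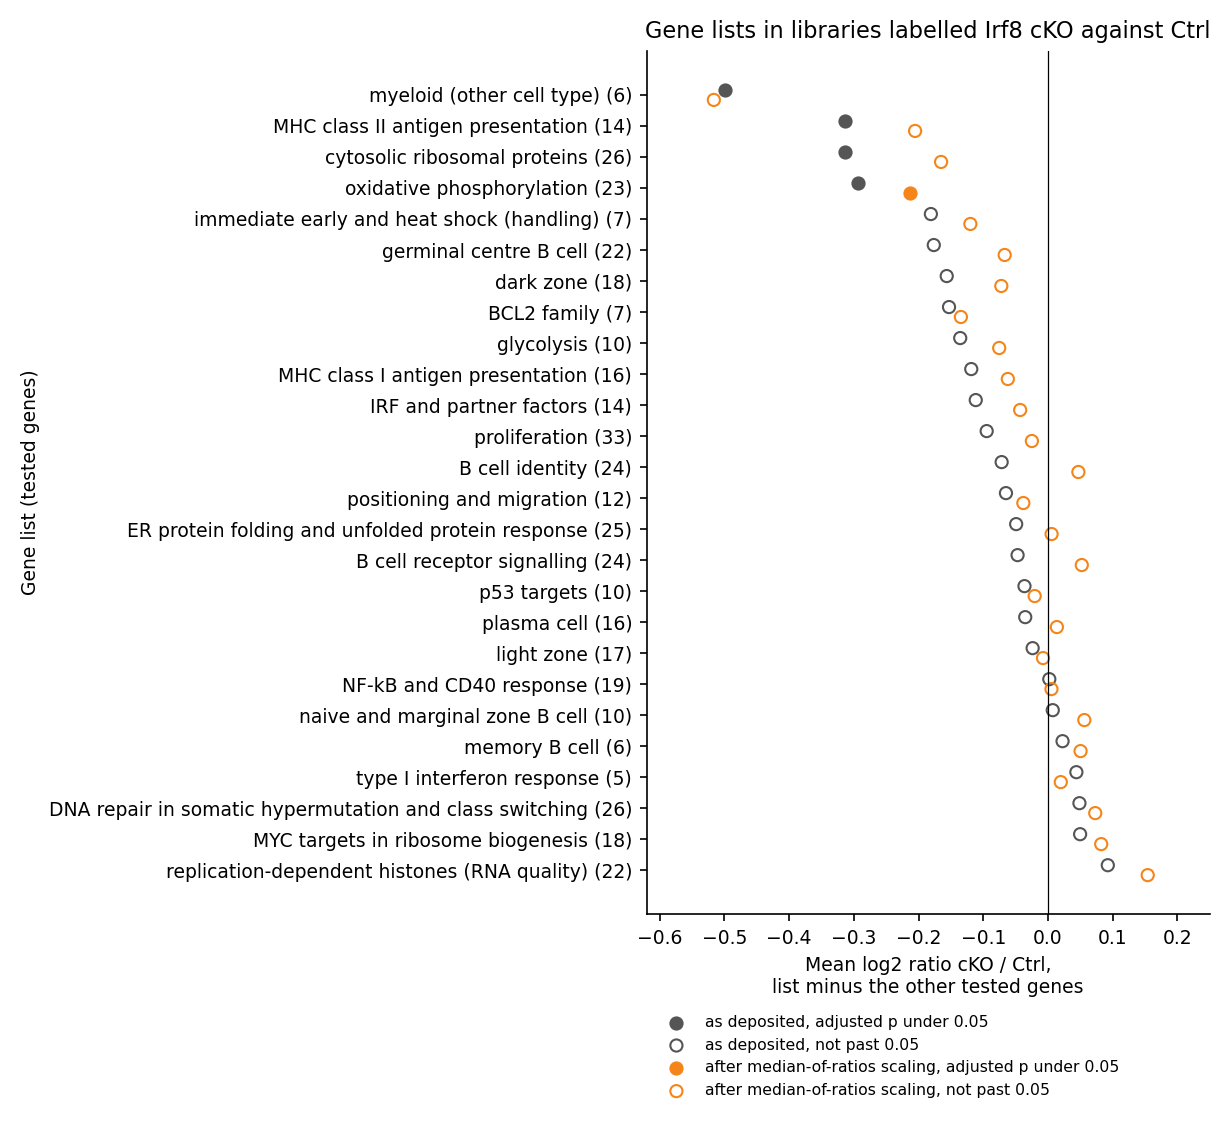
Points give, for 26 gene lists, the mean log2 ratio of the list minus that of the other tested genes, libraries labelled Irf8 cKO over Ctrl, grey as deposited and orange after median-of-ratios scaling, filled where the adjusted p of camera is under 0.05. As deposited 4 lists pass, and after scaling oxidative phosphorylation at -0.21 remains, with 0 lists passing in either when the correlation is estimated, while plasma cell, ER protein folding, B cell identity and B cell receptor signalling lists change from below to above 0.

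Lists of the GC programme did not pass as deposited or after scaling. Of 22 germinal centre B cell genes none passed and 0 did when adjusted over the list alone, with the list at -0.18 as deposited (camera adjusted p = 0.407) and -0.07 after scaling. It passed with no filter on low values (adjusted p = 0.00750) and with no trend in the variance (adjusted p = 0.0230). With no filter, genes near 0 RPKM join the other genes, and their log2(RPKM + 1) barely moves with the shift of the deposited values. An expressed list then lies lower by the shift alone, so such passes are not read as list changes here. S1pr2, the receptor that confines B cells to the follicle centre, measured 11.3 ± 0.740 against 6.62 ± 1.49 RPKM, and Basp1 11.7 ± 0.591 against 5.84 ± 1.97 (mean ± SD, n = 2 each). Of 18 dark zone genes none passed, 0 when adjusted over the list alone, with Polh, a polymerase of somatic hypermutation, at 12.2 ± 2.26 against 7.40 ± 2.30 and Ccna2 at 22.2 ± 8.65 against 13.9 ± 9.31. Of 17 light zone genes none passed and 2 were lower when adjusted over the list alone. Cd52, a lymphocyte surface glycoprotein, measured 79.7 ± 25.3 against 38.3 ± 4.17, and Slamf1 8.38 ± 2.64 against 3.84 ± 0.794. The dark zone list lay at -0.16 (adjusted p = 0.599) and -0.07 after scaling, and it passed with no filter on low values, at -0.33 (adjusted p = 0.00496). The light zone list lay at -0.02 (adjusted p = 0.970) and -0.0076 after scaling. After scaling, the median of the light zone list was 0.03 and its test pointed up, against its mean.

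Of 24 B cell identity genes Ms4a1 fell and 23 did not pass, with 1 lower when adjusted over the list alone. Cd37, a tetraspanin, measured 52.6 ± 8.62 against 27.1 ± 2.47 RPKM and Fcrla 10.5 ± 2.89 against 5.11 ± 1.80 (mean ± SD, n = 2 each). Of 24 B cell receptor signalling genes none passed, 0 when adjusted over the list alone, with Cd79b, a chain of the receptor, at 93.4 ± 11.9 against 57.7 ± 17.2 and Lyn, a kinase of the pathway, at 17.4 ± 0.558 against 9.68 ± 3.79. The identity list lay at -0.07 (camera adjusted p = 0.970) and at 0.05 after scaling. After scaling 13 of its 24 genes lay above 0 in both experiments and 7 below. Adjusted over the list alone, 1 was then higher and 0 lower. The signalling list lay at -0.05 (adjusted p = 0.970), where its test pointed up, and at 0.05 after scaling. Of 10 naive and marginal zone B cell genes none passed and 2 were lower when adjusted over the list alone, Fcer2a and Vpreb3, at 12.3 ± 2.91 against 5.49 ± 0.636 and 17.1 ± 5.43 against 7.59 ± 0.136. Of 6 memory B cell genes none passed, 0 when adjusted over the list alone, with Nt5e at 2.79 ± 0.709 against 1.87 ± 0.643 and Cd44 at 5.21 ± 1.53 against 4.003 ± 0.606. After scaling the log2 ratios of Nt5e and Cd44 were -0.06 and 0.14. These lists lay at 0.0074 and 0.02 (adjusted p = 0.864 and 0.970), and at 0.06 and 0.05 after scaling.

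Plasma cell and IRF lists did not pass either. Of 16 plasma cell genes none passed and 1 was lower when adjusted over the list alone. Eaf2 measured 4.91 ± 0.740 against 2.18 ± 1.14 RPKM and Txndc5 7.99 ± 0.727 against 4.14 ± 1.43 (mean ± SD, n = 2 each). Of 25 genes of ER protein folding and the unfolded protein response none passed, 0 when adjusted over the list alone, with the chaperones Hspa5 at 19.1 ± 4.13 against 12.9 ± 3.40 and Canx at 15.0 ± 4.75 against 9.57 ± 4.54. Of 14 genes of IRF and partner factors none passed, 0 when adjusted over the list alone, with Elf1 at 13.3 ± 2.38 against 7.91 ± 2.14 and Ikzf3 at 52.4 ± 0.475 against 30.6 ± 7.80. The differences were -0.04, -0.05 and -0.11 as deposited (camera adjusted p = 0.970, 0.970 and 0.757) and 0.01, 0.0056 and -0.04 after scaling. The scaled mean of the ER list was above 0 while its median, -0.02, and its test pointed down. With no filter on low values the ER list passed, at -0.19 (adjusted p = 0.0460), which the shift alone can bring about for expressed genes.

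Antigen and stimulus response lists gave these values. Of 16 genes of MHC class I antigen presentation Psmb8 fell and 15 did not pass, with 2 lower when adjusted over the list alone. Psme1, an activator subunit of the proteasome, measured 33.8 ± 5.93 against 17.1 ± 8.57 RPKM (mean ± SD, n = 2 each). Of 5 tested genes of the type I interferon response none passed, 0 when adjusted over the list alone, with Trim30a at 2.81 ± 0.471 against 2.10 ± 0.00480 and Isg20 at 1.81 ± 0.118 against 1.14 ± 0.324. After scaling the log2 ratios of Trim30a and Isg20 were 0.09 and -0.11. Of 19 NF-kB and CD40 response genes none passed, 0 when adjusted over the list alone, with Tnfaip3 at 2.24 ± 0.205 against 1.07 ± 0.0327 and Cd40 at 3.91 ± 0.456 against 2.16 ± 0.240. Of 12 positioning and migration genes none passed, 0 when adjusted over the list alone, with Gna13, which signals downstream of S1pr2, at 15.0 ± 4.54 against 9.21 ± 4.69 and Itgal at 5.74 ± 0.871 against 3.17 ± 0.476. The differences in this order were -0.12, 0.04, 0.0021 and -0.06 as deposited (camera adjusted p = 0.795, 0.970, 0.970 and 0.970) and -0.06, 0.02, 0.0054 and -0.04 after scaling. The median of the NF-kB list after scaling was -0.01, below 0 where its mean and test were above. With no filter on low values the interferon list passed, at 0.13 (adjusted p = 0.0460). Most of its members lay below the filter, and genes near 0 RPKM barely move with the shift. That pass is therefore not read as a rise.

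Of 33 proliferation genes none passed, 0 when adjusted over the list alone, with Pcna at 35.8 ± 13.9 against 21.5 ± 10.4 RPKM and Rrm2 at 15.0 ± 5.93 against 9.63 ± 6.10 (mean ± SD, n = 2 each). Of 26 genes of DNA repair in hypermutation and class switching none passed, 0 when adjusted over the list alone, with H2afx at 46.5 ± 17.4 against 31.8 ± 13.0 and Apex1 at 4.68 ± 1.73 against 3.45 ± 1.44. After scaling the log2 ratios of H2afx and Apex1 were -0.04 and 0.05. Of 10 p53 targets none passed, 0 when adjusted over the list alone, with Ei24 at 2.42 ± 0.945 against 1.28 ± 0.575 and Rrm2b at 7.13 ± 0.507 against 4.12 ± 1.48. Of 7 BCL2 family genes none passed and 1 was lower when adjusted over the list alone, the survival gene Mcl1, at 23.7 ± 6.32 against 10.7 ± 6.29. Of 10 glycolysis genes none passed, 0 when adjusted over the list alone, with Gapdh at 124.8 ± 20.4 against 75.3 ± 25.9 and Ldha at 39.7 ± 11.3 against 23.3 ± 12.3. Of 18 MYC targets in ribosome biogenesis none passed, 0 when adjusted over the list alone, with Odc1 at 11.7 ± 3.90 against 6.82 ± 4.24 and Dkc1 at 6.91 ± 1.14 against 3.94 ± 1.92. The differences in this order were -0.09, 0.05, -0.04, -0.15, -0.14 and 0.05 as deposited (camera adjusted p = 0.765, 0.641, 0.970, 0.641, 0.641 and 0.717) and -0.02, 0.07, -0.02, -0.13, -0.08 and 0.08 after scaling. With no filter on low values the proliferation list passed, at -0.27 (adjusted p = 0.00496), which the shift alone can bring about for expressed genes.

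Lists that report on RNA quality and handling did not pass as deposited or after scaling. The histone list passed under other choices given below, among them quantile normalization and scaling with the length trend removed. Of 22 replication-dependent histone genes, whose transcripts lack poly(A) tails, none passed, 0 when adjusted over the list alone. The list lay at 0.09 as deposited (camera adjusted p = 0.329) and at 0.15 after scaling (adjusted p = 0.170), with -0.13 in experiment 1 and 0.44 in experiment 2. Without Ctrl 1 and without the block it lay at 0.43 as deposited and 0.46 after scaling. Both lie above either experiment alone (-0.16 and 0.35 as deposited), in a fit that mixes in the difference between experiments. Hist1h4d measured 213.8 ± 133.9 against 135.8 ± 70.7 RPKM and Hist1h3b 11.4 ± 2.82 against 7.22 ± 0.821 (mean ± SD, n = 2 each), values that reads shared between near-identical copies can move. Of 7 immediate early and heat shock genes none passed and 2 were lower when adjusted over the list alone, Hspa8 and Hsph1, at 95.4 ± 19.0 against 47.0 ± 21.2 and 11.6 ± 0.852 against 5.02 ± 2.36. That list lay at -0.18 (adjusted p = 0.641) and at -0.12 after scaling.

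Markers of other cells were few. Of 3 tested T cell genes Cd2, an adhesion receptor that mouse B cells carry as well, fell, also when adjusted over the list alone, with a log2 ratio of -1.25 ± 0.30 (limma, adjusted p = 0.00751) and -0.84 after scaling (adjusted p = 0.233). The others, Lck and Cd247, did not pass. Of 4 tested dendritic cell genes (Flt3, Ly6d, Tcf4 and Pacsin1) none passed, 0 when adjusted over the list alone, with Pacsin1 at 1.32 ± 0.479 RPKM in Ctrl and 2.02 ± 0.147 in the libraries labelled Irf8 cKO and Flt3 at 1.49 ± 0.283 against 0.889 ± 0.104 (mean ± SD, n = 2 each). The stromal list had 1 tested gene, Pecam1, and the immunoglobulin list 1, the joining chain gene Igj, at 22.3 ± 9.37 against 16.5 ± 7.69, and neither passed. After scaling the log2 ratio of Igj was 0.07. Only 2 of the 18 immunoglobulin genes have an entry in the deposited values, so the others were not measured here. The NK cell list and the erythroid and platelet list had 0 tested genes. None of these 6 lists reached the minimum of 5 tested genes, so no set test was run.

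The 2 experiments, which share no library, were compared across genes, and genes are not independent replicates. The log2 ratios of 6446 genes correlated with Pearson's r = 0.265 and Spearman's rho = 0.269 as deposited, and 74.0% had the same sign. After scaling r was 0.210, rho 0.207 and 57.6% had the same sign. In the authors' deposited table, 611 of 23467 genes had p under 0.05 in experiment 1 and 533 in experiment 2, each a comparison of 1 library with 1 library. Of the 100 genes with p under 0.05 in both experiments, 92 had the same sign, 43 lower and 49 higher, where 6.92 genes would share a direction if the experiments were independent. The 6.92 is taken over all 23467 genes. Only 12974 to 13801 entries per library lay above 0 RPKM, so it is too low. Havcr1, Kmo, Gatm, Ctsh, Kynu and Reln were among the 43 lower genes of the authors' deposited table, and Scgb1a1, Cd72 and Leng8 among the 49 higher ones. Kynu encodes kynureninase, which acts after Kmo in tryptophan breakdown, and fell from 2.87 ± 0.478 to 0.813 ± 0.407 RPKM (mean ± SD, n = 2 each) in the deposited values. Its log2 ratio was -1.11 ± 0.26 (limma, adjusted p = 0.00407), and -0.82 after scaling (adjusted p = 0.172). As deposited, the call of Kynu also ended without the block (limma adjusted p = 0.0569) and with no filter (0.198). Kynu and Reln were chosen after their values were seen.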

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

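The pairs of choices (median-of-ratios scaling together with no block, with pseudocount 0.1, with the length or the GC trend removed, with an adjusted p under 0.1, with a 2-fold limit, or with a library left out) were chosen only after the results were seen, as was median-of-ratios scaling for the agreement of the experiments. Irf8 stayed above 0 and uncalled under the alternatives with all 4 libraries, and the 10 genes named lower stayed past the threshold with pseudocount 0.1, with no trend in the variance and with the highest transcript value per symbol. Pseudocount 5 ended the call of Ms4a1, and the filter at RPKM 5 that of Cd74 and removed S100a8 and S100a9. With no filter none of the 10 passed (Havcr1 at adjusted p = 0.0614), and without the block Havcr1, S100a8 and S100a9 did. Under both settings the 10 log2 ratios equal those of the main fit by construction. The highest transcript value per symbol changed no result, and it could hardly do so, as only 2 symbols have more than 1 entry. The 4 calls after median-of-ratios scaling are among the 76 as deposited, and the 21 calls without the block all are. With an estimated correlation, which rests on 1 residual degree of freedom, 0 lists passed, as deposited or after scaling. Except where fewer genes or libraries entered by construction, or where scaling takes out the shift of the median, the cause was not tested for any change listed here. The count tests planned in case reads were recovered (edgeR and DESeq2) were not run, because 68.0% to 69.9% of the low values came out whole within 0.1 reads. Low depth in the library labelled Irf8 cKO 2, at an estimated 4.53 M exonic reads, limits the genes under 1 RPKM.

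Pseudocount 5 gave 124 lower genes, ribosomal proteins at -0.41 (limma camera adjusted p = 0.0618) and an agreement of r = 0.40. A pseudocount of 0.1 kept the counts within 1.5 times. With no filter, limma called 0 higher and 0 lower genes of 15557 (292 and 1694 at an unadjusted p under 0.05), the myeloid list lay at -0.13 and r was 0.38. The lists of germinal centre B cell, dark zone, proliferation, ER folding and interferon response genes then passed (adjusted p = 0.00750, 0.00496, 0.00496, 0.0460 and 0.0460). Genes near 0 RPKM barely move with the shift of the deposited values. Once they enter, expressed lists lie lower and lists of low genes higher, so these passes cannot be told from the shift. With RPKM of 5 or more there were 0 higher genes (limma, 2 at an unadjusted p under 0.05) and 26 lower, with MHC class II at -0.22 and oxidative phosphorylation at -0.15, neither past the threshold. Without a trend in the variance 277 genes were lower and the germinal centre B cell list passed (adjusted p = 0.0230). At an adjusted p under 0.1 there were 7 higher and 131 lower genes as deposited, and 7 and 8 after median-of-ratios scaling. At least 2-fold in both experiments were 1 higher and 24 lower genes as deposited, and 6 and 8 after scaling.

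Median-of-ratios scaling gave 1 higher and 3 lower genes and quantile normalization 2 and 4. Lists that no longer passed were MHC class II (-0.21 and -0.13 under these scalings), ribosomal proteins (-0.17 and -0.043) and myeloid (-0.52 and -0.48). Scaling together with pseudocount 0.1 gave 0 and 0 genes (limma, 373 higher and 281 lower at an unadjusted p under 0.05), with MHC class II at -0.21, ribosomal proteins at -0.17 and myeloid at -0.65. Scaling with the length trend removed gave 0 and 0 of 6383 genes (limma, 345 higher and 283 lower at an unadjusted p under 0.05). Its lists lay at -0.16 for MHC class II, -0.16 for oxidative phosphorylation, -0.091 for ribosomal proteins and -0.56 for myeloid, none past the threshold. Scaling with the GC trend removed gave 8 higher and 13 lower genes, among them Havcr1 and Ctsh of the genes named lower. MHC class II, at -0.22, did not pass, while oxidative phosphorylation (-0.22), ribosomal proteins (-0.18) and myeloid (-0.64) did.

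The experiments pair the samples, and the fit without that replicate block gave 2 higher and 19 lower genes. It ended the calls of MHC class II (-0.31), oxidative phosphorylation (-0.29) and ribosomal proteins (-0.31), with camera adjusted p of 0.899, 0.10 and 0.969. No block together with scaling gave 2 higher and 4 lower genes, with MHC class II at -0.21, ribosomal proteins at -0.17 and myeloid at -0.52 not past the threshold.

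Values called in neither setting changed sign as follows. With pseudocount 0.1 they were the lists of plasma cell (0.018), B cell identity (0.035), light zone (0.013) and B cell receptor signalling (0.037) genes. With pseudocount 5 they were naive and marginal zone (-0.053), memory (-0.020) and histones (-0.0034). With no filter they were DNA repair (-0.13), NF-kB (-0.11), naive and marginal zone (-0.053), MYC targets (-0.079) and histones (-0.086). With RPKM 5 or more they were plasma cell (0.030), ER folding (0.047), B cell identity (0.090), proliferation (0.030), NF-kB (-0.087), naive and marginal zone (-0.097) and B cell receptor signalling (0.11). Median-of-ratios scaling, with or without the block, turned Irf4 (0.39), Xbp1 (0.054), Bcl6 (0.0080), Pax5 (0.47), Sfpi1 (0.19) and Ciita (0.070). It also turned plasma cell (0.014), ER folding (0.0056), B cell identity (0.047) and B cell receptor signalling (0.052). Quantile normalization turned Irf4 (0.39), Xbp1 (0.078), Bcl6 (0.12), Pax5 (0.57), Sfpi1 (0.21) and Ciita (0.10). Its lists were plasma cell (0.034), ER folding (0.027), B cell identity (0.12), proliferation (0.0082), NF-kB (-0.0055) and B cell receptor signalling (0.094). Scaling with pseudocount 0.1 turned Irf4 (0.48), Xbp1 (0.063), Bcl6 (0.0080), Pax5 (0.49), Sfpi1 (0.22) and Ciita (0.081). Its lists were plasma cell (0.026), B cell identity (0.057), light zone (0.017), p53 targets (0.0020) and B cell receptor signalling (0.056). Scaling with the length trend removed turned Irf4 (0.35), Xbp1 (0.071), Pax5 (0.39), Sfpi1 (0.21) and Ciita (0.027). Its lists were plasma cell (0.034), ER folding (0.0049), B cell identity (0.046), light zone (0.015) and B cell receptor signalling (0.047). Scaling with the GC trend removed turned Irf4 (0.41), Xbp1 (0.035), Bcl6 (0.0035), Pax5 (0.48), Sfpi1 (0.091) and Ciita (0.0031). Its lists were plasma cell (0.014), ER folding (0.014), B cell identity (0.032), p53 targets (0.0016), NF-kB (-0.020) and B cell receptor signalling (0.040).

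Leaving out an experiment gives a single ratio with no test, and leaving out a library needs the fit without the block, in which the lone sample is assumed to vary like the other group. The ratio of such a fit also mixes in the difference between experiments. The ranges below cover a left-out experiment as deposited and a left-out library as deposited and after scaling. Higher genes ranged from 0 to 13 and lower genes from 0 to 1450. At 0 higher and 0 lower, as deposited without Ctrl 1, limma gave 7 and 31 at an unadjusted p under 0.05. Irf8 ranged from -0.33 to 0.66, Irf4 from -0.18 to 0.61, Xbp1 from -0.67 to 0.23 and Bcl6 from -0.68 to 0.16. Pax5 ranged from -0.27 to 0.89, Sfpi1 from -0.39 to 0.40, Spib from -0.85 to 0.033, Ciita from -0.60 to 0.31 and S100a8 from -3.38 to 0.13. Arhgef1 ranged from -0.068 to 1.11, Nfatc1 from -0.095 to 0.73, Fnbp4 from -0.027 to 1.09, Ankrd11 from -0.16 to 1.17, Map4k2 from -0.045 to 1.09 and Depdc5 from -0.020 to 0.86. After scaling over all 4 libraries, single experiments went past some of these ranges, with Irf8 at 0.72 in experiment 1, and Irf4 at 0.69, Xbp1 at 0.30, Spib at 0.13 and Nfatc1 at 0.83 in experiment 2. The called lists ranged from -0.33 to -0.13 (MHC class II), -0.55 to 0.022 (oxidative phosphorylation), -0.53 to 0.025 (ribosomal proteins) and -1.14 to 0.14 (myeloid). Ribosomal proteins, plasma cell and ER folding lay at 0.05, 0.095 and 0.13 in experiment 2 after scaling over all 4 libraries. The B cell lists ranged from -0.14 to 0.0043 (IRF and partner factors), -0.13 to 0.093 (plasma cell), -0.15 to 0.095 (ER folding), -0.16 to 0.15 (B cell identity) and -0.16 to 0.16 (B cell receptor signalling). Dark zone genes ranged from -0.35 to 0.067, light zone from -0.13 to 0.097, naive and marginal zone from -0.095 to 0.16 and memory from -0.062 to 0.11. Positioning ranged from -0.13 to 0.013, NF-kB from -0.15 to 0.15, MHC class I from -0.19 to 0.048 and interferon response from -0.039 to 0.11. Proliferation ranged from -0.32 to 0.15, BCL2 family from -0.38 to 0.081, glycolysis from -0.31 to 0.056, MYC targets from -0.089 to 0.19 and histones from -0.24 to 0.46. The histone list, not called in the main values, passed without Ctrl 1 as deposited (0.43) and after scaling (0.46), without the library labelled Irf8 cKO 2 after scaling (0.19), with quantile normalization (0.23) and with scaling and the length trend removed (0.22).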

Other observations

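The tests of exonic share, 45S reads, exchanged libraries and the standing of Ctrl 1 were chosen only after the result was seen.

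In the authors' deposited table, the 92 genes with p under 0.05 and the same sign in both experiments include Ddx58, Ddx60, Parp12 and Tgtp2, chosen after their values were seen. No list holding these 4 together was tested, so no shared function is claimed for the 92. Ddx58, which encodes the RNA sensor RIG-I, had log2 ratios of 1.71 and 1.71 in experiments 1 and 2 of the authors' deposited table. Ddx60, a helicase induced by interferon, had 4.67 and 5.83, Parp12, an ADP-ribosyltransferase, 4.88 and 5.66, and Tgtp2, an immunity-related GTPase, 2.59 and 4.54. Their values in Ctrl 1 and 2 were near the floor, so these ratios are imprecise. They were 0.0045 and 0.0053 RPKM for Ddx60, 0.0084 and 0.0098 for Parp12, and 0.068 and 0.022 for Tgtp2. All 4 genes lay below 1 RPKM in the 4 libraries, with Ddx58 highest, at 0.931 in the library labelled Irf8 cKO 1 and 0.908 in the library labelled Irf8 cKO 2, against 0.327 and 0.456 in Ctrl. Of 27 genes of the fixed type I interferon list with values in the authors' deposited table, 1 (Ddx58) was higher in both experiments and 0 were lower, and that list did not pass in the deposited RPKM (camera adjusted p = 0.970). Only 5 of the 27 were tested there, without Ddx58, and with no filter on low values the list passed, at 0.13 (adjusted p = 0.0460). Genes near 0 RPKM barely move with the shift of the deposited values, so a list of low genes can pass upward by that shift alone. Nlrc5, the transactivator of MHC class I, was higher in both (0.93 and 1.06), while Psmb8 of the same list was lower in both.

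In the same deposited table of the authors, the survival gene Mcl1 was lower in both experiments, at -0.69 and -0.90, the only one of 17 BCL2 family genes with p under 0.05 in both. Genes lower in both and outside the fixed lists include Rnase6, a ribonuclease gene, at -2.28 and -1.64, Sepp1, which encodes selenoprotein P, at -1.88 and -1.48, and Cd36, a scavenger receptor gene, at -1.74 and -3.06. Higher in both were Ptpn22, a phosphatase of antigen receptor signalling, at 2.63 and 1.86, and Trpm5, a cation channel gene, at 2.02 and 1.94. These values compare 1 library with 1 library in each experiment. Rnase6, Sepp1, Cd36, Ptpn22 and Trpm5 were chosen after their values were seen. Cd36 and Ptpn22 lay below the filter, so their ratios are imprecise. Cd36 measured 1.28 and 0.886 RPKM in Ctrl 1 and 2 against 0.339 and 0.0687 in the libraries labelled Irf8 cKO. Ptpn22 measured 0.389 and 0.404 against 2.08 and 0.891.

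More genes were lower than higher in the deposited RPKM of the libraries labelled Irf8 cKO. Reads counted for the Rn45s entry were argued against as the cause: alone they shift the log2 values by -0.098 in experiment 2 and by 0.0044 in experiment 1. Ribosomal RNA reads that fell outside that entry are not counted in it, so ribosomal RNA as a whole stays open. A smaller share of reads in annotated exons may account for the displacement, since the log2 ratio of the exonic shares (-0.26 and -0.68) came within 0.057 of the library shift in both experiments, where that shift is the constant between the authors' deposited log2 ratio and the RPKM ratio (0.205 and 0.721) with its sign turned. From the median log2 ratios of -0.18 and -0.51 the shares lie further away. That share is computed from the same RPKM, so it locates the shift and says nothing of its origin. RNA input, amplification, or less mRNA per cell in these mice stay open, as no spike-in is used here and the biological explanation was not tested.

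The oxidative phosphorylation list was lower after median-of-ratios scaling, at -0.21 with a member SD of 0.18 (camera adjusted p = 0.00812, and 0.972 with an estimated correlation). GC content was argued against as the whole cause, since the list lay at -0.22 with adjusted p = 0.0031 (camera) after that trend was removed. With the same trend removed ribosomal proteins (-0.18, adjusted p = 0.0274) and the myeloid list (-0.64, adjusted p = 0.00872) passed as well. Transcript length may be part of it: with its trend removed the list lay at -0.16, member SD 0.18, and the call ended (adjusted p = 0.085) with the smaller difference, so length stays open. Across genes the log2 ratios correlated with transcript length at a Spearman's rho of 0.29 in experiment 1 and 0.05 in experiment 2. The list had a median length of 1079 bases, against 2884 for all genes with a length. Its difference was larger in experiment 1 as well, at -0.34. Ctrl 1 standing apart may be a cause as well, and the same library holds the most S100a8 and Lcn2. Without it the list lay at 0.022, but that fit has no block and compares libraries of both experiments with Ctrl 2 alone. The difference between experiments enters there, so the value cannot decide. Within experiment 2, which lacks Ctrl 1, the list lay at -0.08. On the log2 scale Ctrl 1 correlated with the other libraries at 0.908 to 0.961, and the library labelled Irf8 cKO 2 at 0.908 to 0.943. With Ctrl 1 kept, the list lay at -0.11 without the library labelled Irf8 cKO 2 (adjusted p = 0.336) and at -0.45 without Ctrl 2, values that do not count against Ctrl 1 as a cause. Loss of IRF8 itself, which the design names, was not told from these by any test run here.

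Irf8 was not lower in the libraries labelled Irf8 cKO. An exchange of the Ctrl and Irf8 cKO libraries in 1 experiment was argued against, since 92.0% of the 100 genes past the authors' p in both experiments had the same sign, where an exchange would turn most of them. An exchange in both experiments would leave the signs alike and stays open. Reads from exons outside the loxP sites stay open too, because 1 value per gene covers all exons, as does incomplete deletion in the sorted cells, for which no value per exon is used here.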
